A study of Mus musculus with 11 samples.

How the data were processed

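Liver mRNA of 11 C57BL/6 mice on a methionine- and choline-deficient (MCD) diet was sequenced, with 5 libraries of the MCD group and 6 of the limonin group, each from 1 animal. Per the labels' protocols, poly(A) RNA from samples with an RNA integrity number above 7.0 was fragmented and made into libraries with dUTP in the second strand, which UDG then removed, a procedure that marks the strand. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used, and the build named there is GRCh38, a human build, although the gene identifiers in the table are those of mouse. Whether the strand was used in quantification is not given in the sources used here.

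The deposited table holds FPKM per gene and library, per the file headers. It also holds the authors' ratio of group means (fold change), its log2, and a p-value and q-value per gene, per the file headers; the authors' test is not given in the sources used here. The deposited q equalled the Benjamini-Hochberg adjustment of the deposited p for all 31280 genes, and the authors' marks of significance equalled a q under 0.05 with a change of at least 1.5-fold. Counts were not used here, so no count model was fitted. FPKM divide by the length of the transcript and the depth of the library, so they do not hold the number of fragments behind a value. In genes with 1 transcript, the most frequent low product of FPKM and transcript length was read as 1 fragment. This gave an implied depth of 15630000 fragments (MCD 3) to 19890000 fragments (limonin 3). The search covered a fixed range, so a depth outside that range could not be found. No counting intervals are given.

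FPKM were transformed to log2(FPKM + 1), and genes with at least 1 FPKM in at least 5 libraries were kept, 10489 of 31280. A fold change on this scale understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (trend, robust), with a two-sided moderated test and the Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Values are given as mean ± SD of FPKM and as log2 fold change, limonin minus MCD, ± SE. The procedure was tested on simulated data with 200 of 10489 genes changed in a comparison of 5 and 6 libraries. It recovered 70.1% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold. It made 12 false calls (6.4%), and called 0 genes when nothing was changed. The simulated noise was independent between genes, with no batch and no difference in scaling between libraries. These rates therefore do not give the error rate in the real data.

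Of 41 lists of genes, 4 had too few tested members for a list test. The others were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. The Benjamini-Hochberg adjustment ran over the 35 lists of pathways and cell types with at least 5 tested members. Sums over gene families and tissues were compared by exact permutation over all splits of the libraries into 5 and 6, two-sided. Pathway terms (KEGG) were taken from the deposited table and tested with Fisher's exact test, one-sided, against the 4222 tested genes that have a term; this test treats genes as independent. Coordinates are from GENCODE M21 (GRCm38), in which 31191 of the 31280 gene identifiers were found.

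Groups, tests, the 41 lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took the 12 genes with the largest log2 fold change in each direction among those called with a mean of at least 1 FPKM, leaving out predicted genes, and up to 4 genes with the smallest p of each list. The design had allowed for counts or for FPKM, and the FPKM test was used. Alternatives were no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 0.01, median-ratio and quantile scaling, no trend, weights per library, the replicate number as a block, each library left out, and the authors' deposited calls. Alternatives chosen after seeing the data left out limonin 5 and 6, MCD 4 and 5 or genes of other tissues, removed trends on length and GC content, or scaled libraries to equal summed FPKM. The lists of spermatid, gland, heart and brain genes were also drawn up after seeing the data.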

Results

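Liver RNA was sequenced from 11 C57BL/6 mice kept for 8 weeks on a methionine- and choline-deficient (MCD) diet, which withholds 2 nutrients used to export fat from the liver and serves as a mouse model of steatohepatitis, that is, fatty liver with inflammation and scarring. In the MCD group, 5 mice received water, and in the limonin group 6 mice received limonin, a bitter triterpenoid of citrus fruit, at 100 mg/kg for 4 weeks. Each library was 1 animal, so p-values measure the spread between animals. Mice on a complete diet were not analysed here, so every difference is between limonin and water under the same diet. Expression was given in FPKM (fragments normalized to transcript length and library depth). The most frequent low product of FPKM and transcript length, read as 1 fragment, implied 15630000 to 19890000 fragments per library. Between 9742 and 11087 genes per library reached 1 FPKM.

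The question was which liver genes differ with limonin during MCD feeding. Most tested genes of the matrix, interferon and antigen presentation lists fell in the limonin livers, and 9 of 20 markers of the hepatocyte, the main liver cell, rose. Most tested genes of the bile duct and cytokine lists also fell, but without MCD 2 those called lower were 4 of 9 and 10 of 20. Of 10489 genes tested, 2716 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 759 higher and 1957 lower. A change of at least 2-fold was found in 281 of them, 50 higher and 231 lower. Cib3 (calcium and integrin binding family member 3) was among the 12 largest decreases. It fell from 15.3 ± 6.06 FPKM (SD, n = 5) to 2.13 ± 0.737 (SD, n = 6), a log2 fold change of -2.33 ± 0.23 (SE). Sult2a2, a bile acid and steroid sulfotransferase, fell from 17.9 ± 11.4 to 1.21 ± 0.900 FPKM, a log2 fold change of -2.87 ± 0.49. Both lay below every MCD library in 6 of 6 limonin libraries. The antimicrobial peptide gene Wfdc21 rose from 11.8 ± 2.99 to 79.3 ± 72.4 FPKM, with a log2 fold change of 2.26 ± 0.52 and 6 of 6 limonin libraries above every MCD library. Its adjusted p was 0.0125, and 0.0581 in the fit that left out MCD 4 and 5 and 0.0626 with the replicate number as a block.

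The balance of higher and lower calls depended on the scaling of the libraries. Higher calls made up 27.9% in the deposited FPKM, 48.2% after median-ratio scaling, 52.9% after quantile normalization and 49.5% after scaling to equal summed FPKM, while the median log2 fold change over all genes was -0.07, 0.01, 0.03 and 0.03. Without MCD 2 the number of changed genes was 1408, with 328 higher, 1080 lower and 171 changed at least 2-fold, and without MCD 1 the number of higher genes was 474.

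**Figure D1:**
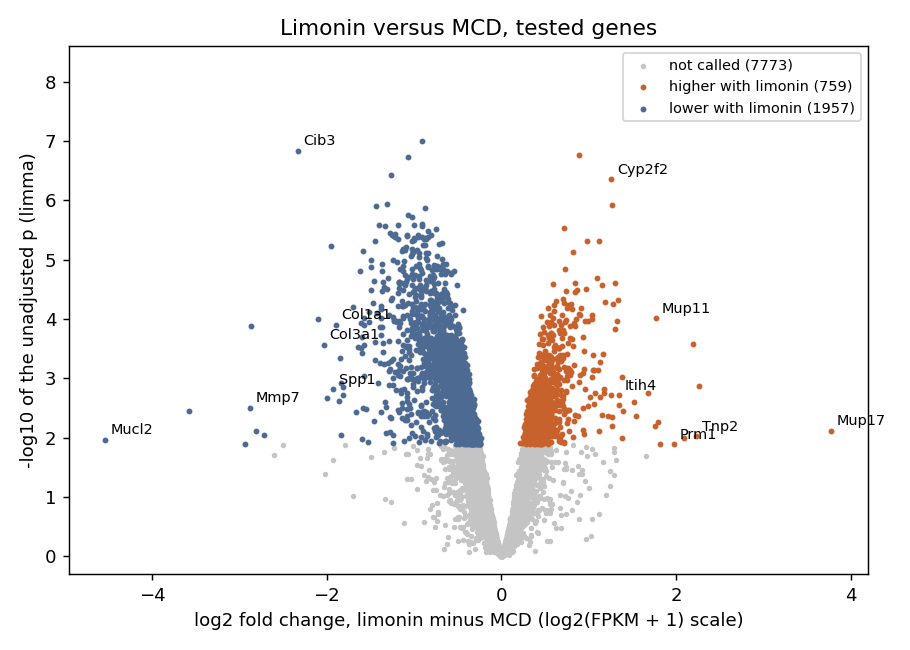
Each point is 1 of the 10489 tested genes, with the log2 fold change of limonin against MCD on the x axis and the -log10 of the unadjusted limma p on the y axis. The 1957 genes called lower outnumber the 759 called higher, and the named genes Mup17 and Mucl2 lie farthest to each side.

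Most tested genes of the extracellular matrix, the scaffold laid down in fibrosis, fell with limonin. Of 26 tested members of the matrix and fibrosis list, 22 fell, 1 rose and 3 did not pass the test (23 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.01. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042, GRCm38), fell from 16.0 ± 7.09 FPKM (SD, n = 5) to 3.38 ± 1.42 (SD, n = 6). Its log2 fold change was -1.89 ± 0.34 (SE) with an adjusted p of 0.00366, and all 6 limonin libraries lay below all 5 MCD libraries. Col3a1, a chain of type III collagen (chromosome 1, 45311538 to 45349706), fell by 2.03 ± 0.39 on the log2 scale. The proteoglycan gene Bgn fell by 1.14 ± 0.17 and the metalloproteinase inhibitor gene Timp2 by 0.94 ± 0.15. The 1 member that rose was Fn1, which encodes fibronectin, a matrix protein that hepatocytes also secrete into plasma, with a log2 fold change of 0.70 ± 0.19; it was named after its values were seen.

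Markers of scar-forming and bile duct cells also fell. Of 16 tested markers of stellate cells and fibroblasts, the collagen-producing cells of the liver, 12 fell and 4 were not called (13 lower adjusted over the list alone), among them Vim, which encodes vimentin, at -1.28 ± 0.17 and Pdgfrb, a growth factor receptor, at -0.96 ± 0.17. Of 9 tested cholangiocyte (bile duct cell) markers, of 16 listed, 8 fell and 1 was not called (8 lower adjusted over the list alone). Epcam, an epithelial adhesion protein, fell from 10.1 ± 5.46 FPKM to 2.50 ± 1.37, a log2 fold change of -1.61 ± 0.32, and the keratin gene Krt19 fell by 1.29 ± 0.28. Mmp7, a metalloproteinase of bile duct epithelium, fell by 2.88 ± 0.74 with an adjusted p of 0.0205, which became 0.0604 without MCD 2. The call was also lost without both limonin 5 and 6 and with the replicate number as a block. Of the 8 cholangiocyte calls 4 remained without MCD 2 and 5 without MCD 1. Of 15 endothelial markers 3 fell, 1 rose and 11 were not called (3 lower and 1 higher adjusted over the list alone), with a median of -0.09. There, 1 was lower without MCD 2, 3 or 5 or limonin 2, 3, 4 or 6. The 1 that rose, Kdr, a growth factor receptor, lost its call without MCD 1, 2 or 5 or limonin 1, 2, 3, 4 or 6 (largest adjusted p 0.122). The matrix, stellate and cholangiocyte lists were called lower by camera, a test of a list against all other genes, with adjusted p of 1.56e-09, 3.34e-06 and 0.00023 at a preset correlation between genes of 0.01. With an estimated correlation their adjusted p were 0.279, 0.145 and 0.279, so these calls were lost. The endothelial list was not called (adjusted p = 0.893, and 0.951 with an estimated correlation).

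**Figure D2:**
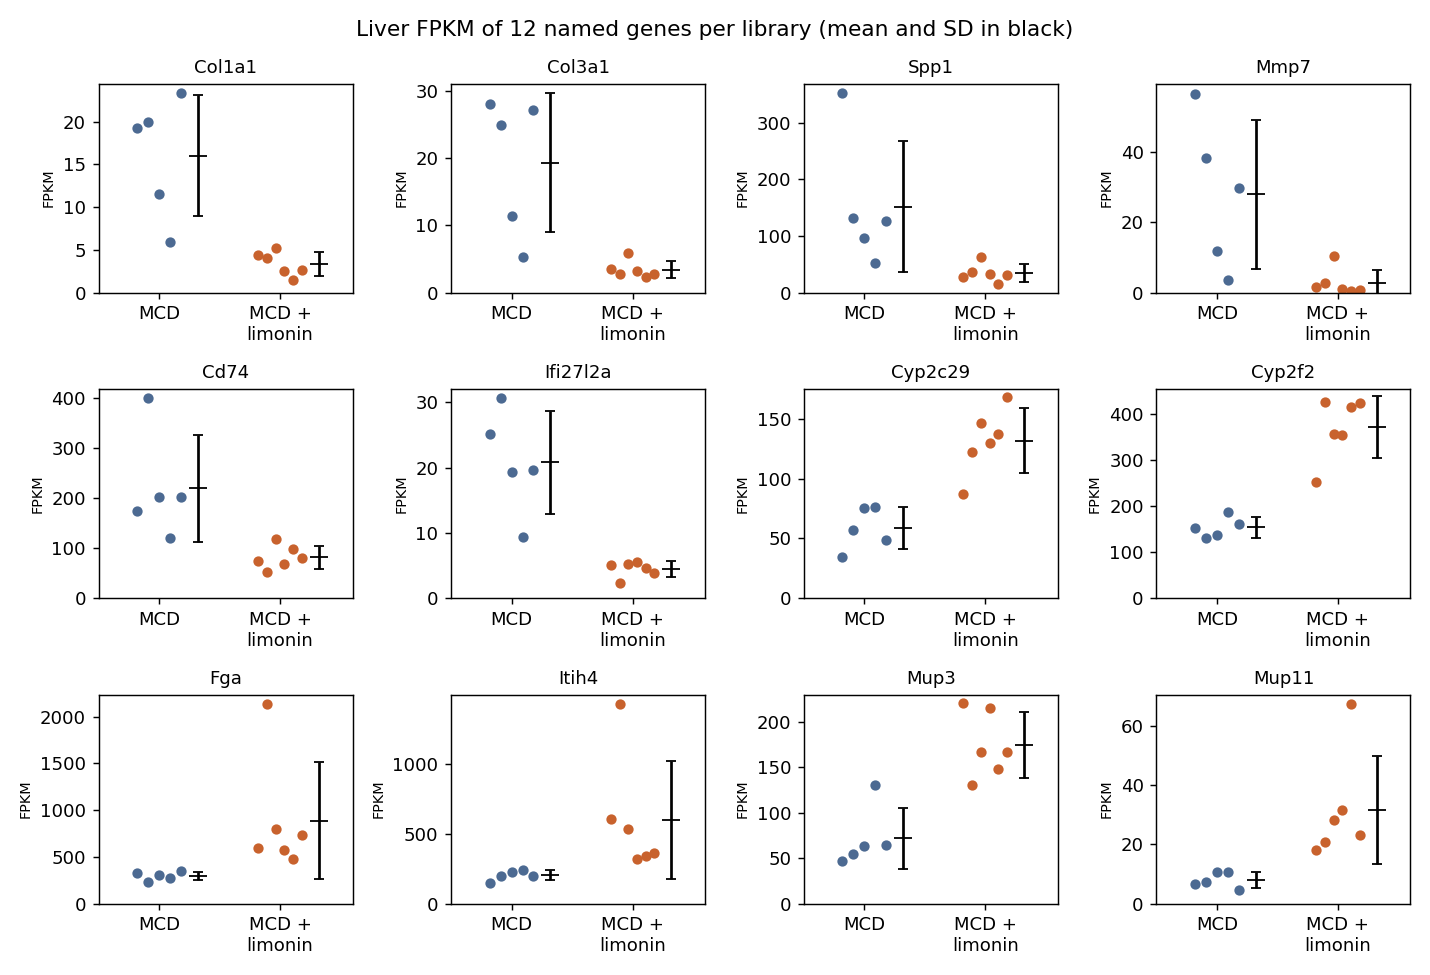
FPKM per library of 12 named genes in the MCD group (n = 5) and the limonin group (n = 6), on linear axes that start at 0, with the mean and SD in black (the lower end of the Mmp7 bar for limonin is cut off at 0). The 6 limonin libraries lie below all MCD libraries for Col1a1, Cd74 and Ifi27l2a and above them for Cyp2c29, Cyp2f2, Fga, Itih4, Mup3 and Mup11.

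Genes of inflammation and of immune cells fell in several lists. Of 20 tested cytokine and NF-kappaB target genes, 16 fell and 4 were not called (17 lower adjusted over the list alone), with a median of -0.93. Ccl2, a chemokine that recruits monocytes, fell from 7.18 ± 1.49 FPKM (SD, n = 5) to 2.23 ± 1.52 (SD, n = 6), and Nfkb2 and Relb, subunits of the NF-kappaB transcription factor, fell by 1.12 ± 0.16 and 1.12 ± 0.19. Of 19 interferon-stimulated genes, 15 fell and 4 were not called (15 lower adjusted over the list alone). The largest fall was that of Ifi27l2a, at -1.95 ± 0.26 with an adjusted p of 0.0013, and Irf7, a transcription factor of the interferon response, fell by 1.08 ± 0.15. The ubiquitin-like gene Ubd, induced by inflammatory cytokines, fell from 24.1 ± 12.3 to 5.79 ± 5.54 FPKM with an adjusted p of 0.0165, which became 0.0508 without MCD 2, where 10 of the 16 cytokine and NF-kappaB genes were called lower.

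Of 16 markers of recruited and lipid-associated macrophages, 11 fell and 5 were not called (13 lower adjusted over the list alone). Spp1, which encodes osteopontin and is also on the cholangiocyte list, fell from 152 ± 117 to 34.8 ± 15.7 FPKM, a log2 fold change of -1.92 ± 0.45 with 5 of 6 limonin libraries below every MCD library. Of 12 markers of Kupffer cells, the resident macrophages, 4 fell, 1 rose and 7 were not called (4 lower and 1 higher adjusted over the list alone). C1qa, a complement component made by macrophages, fell by 1.13 ± 0.26, and the iron exporter gene Slc40a1 rose by 0.64 ± 0.15. All 6 tested dendritic cell and MHC class II genes fell, of 15 listed, among them Cd74, the MHC class II invariant chain, at -1.35 ± 0.28. They moved together, with an estimated correlation of 0.956. All 6 tested B and plasma cell genes fell, of 16 listed, among them Ighm at -1.03 ± 0.20 (6 lower in both lists adjusted over the list alone). In lists too small for a list test, 3 of 4 tested T and NK cell genes and 3 of 4 tested neutrophil genes fell, of 22 and 15 listed (4 lower in each adjusted over the list alone). The filter asked for 1 FPKM in 5 libraries, which the 5 MCD libraries alone could meet. A low gene could thus enter by being high in MCD, so these shares may partly follow from the filter. Ighd, for example, ran from 1.02 to 1.95 FPKM in MCD and from 0.22 to 1.1 with limonin. The same limit applies to other lists. Tested were 26 of 34 listed matrix genes, 9 of 16 cholangiocyte markers and 13 of 28 proliferation genes. For the cytokine and interferon lists, 20 of 31 and 19 of 29 were tested. Of 13 proliferation genes 8 fell and 5 were not called (11 lower adjusted over the list alone), among them the replication helicase genes Mcm3 at -0.87 ± 0.20 and Mcm6 at -0.69 ± 0.18, whose call was lost with no filter (adjusted p = 0.0573).

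Several of these counts rested on single libraries. Without MCD 2, genes called lower numbered 4 of 16 for recruited macrophages, 2 of 12 for Kupffer cells, 2 of 6 for B and plasma cells, 0 of 4 for neutrophils and 2 of 13 for proliferation. Recruited macrophage genes called lower numbered 7 without MCD 1 or limonin 2, and B and plasma cell genes 3 without MCD 3, MCD 4, limonin 4 or limonin 6. Proliferation genes called lower numbered 2 without limonin 2 and 3 without MCD 5 or limonin 6. They numbered 4 without MCD 1, limonin 1, limonin 4 or limonin 5, and 5 without MCD 3.

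At the preset correlation camera called lower the cytokine list (adjusted p = 1.3e-06), the interferon list (1.3e-06), the macrophage list (0.000133), the MHC class II list (0.00034), the B cell list (0.00383) and the proliferation list (0.00112). With an estimated correlation the adjusted p were 0.279, 0.279, 0.363, 0.302, 0.279 and 0.495, and no call remained. The Kupffer list was not called (adjusted p = 0.147, and 0.743 with an estimated correlation), but it was called without MCD 1, where the adjusted p was 0.0024, and at equal summed FPKM (0.042).

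Of 20 hepatocyte markers 9 rose and 11 were not called (9 higher and 1 lower adjusted over the list alone), with a median of 0.39. Fga, a fibrinogen chain (chromosome 3, 83026076 to 83033627, GRCm38), rose from 297 ± 44.5 FPKM (SD, n = 5) to 887 ± 625 (SD, n = 6), a log2 fold change of 1.38 ± 0.32 with 6 of 6 limonin libraries above every MCD library. Cps1, the entry enzyme of the urea cycle, rose by 1.05 ± 0.23. Of 18 genes of periportal hepatocytes, those near the incoming blood, 8 rose and 10 were not called (9 higher adjusted over the list alone), and 5 were called higher without MCD 2. Cyp2f2, a cytochrome P450, rose from 153 ± 22.3 to 371 ± 66.8 FPKM, a log2 fold change of 1.26 ± 0.15 with an adjusted p of 0.000778, and Hal, a histidine-degrading enzyme, rose by 1.10 ± 0.18. Of 17 genes of pericentral hepatocytes 2 rose, 2 fell and 13 were not called (2 higher and 2 lower adjusted over the list alone), with Cyp2c29 at 1.19 ± 0.21 and the Wnt pathway gene Nkd1 at -0.46 ± 0.13; the call of Nkd1 was lost without MCD 2 (adjusted p = 0.0700), where 0 pericentral genes were lower. The count was 1 without limonin 2, 4 or 6 and 4 without limonin 1. The call of Nkd1 was also lost with no filter, with quantile normalization, at equal summed FPKM, after removal of length and GC trends and without both MCD 4 and 5 (largest adjusted p 0.0841).

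Some genes of lipid, bile acid and drug metabolism also rose. Of 33 fatty acid oxidation genes 12 rose, 1 fell and 20 were not called (15 higher and 1 lower adjusted over the list alone), with a median of 0.21. Cyp4a14, an omega-hydroxylase of fatty acids, rose from 474 ± 89.1 FPKM (SD, n = 5) to 778 ± 97.1 (SD, n = 6), and Acsl1, which activates fatty acids, rose by 0.81 ± 0.15. The member that fell was Fgf21, a hormone induced by fasting and stress, at -1.53 ± 0.50 with an adjusted p of 0.0474; 9 of the 11 fits without 1 library lost this call (largest adjusted p 0.117), and those without limonin 3 or limonin 4 kept it. Of 22 bile acid genes 8 rose, 1 fell and 13 were not called (8 higher and 1 lower adjusted over the list alone), among them Abcg8, a sterol exporter, at 0.84 ± 0.16 and Cyp7b1, an enzyme of the alternative bile acid pathway, at 0.70 ± 0.14. The member that fell was the transporter subunit gene Slc51b, at -0.76 ± 0.20. Fgf21 and Slc51b were named after their values were seen. Of 29 targets of the xenobiotic receptors PXR and CAR, 11 rose and 18 were not called (12 higher adjusted over the list alone), among them Cyp2c29 and the glucuronosyltransferase gene Ugt2b35, at 0.82 ± 0.12. Of 29 methionine, choline and one-carbon genes 10 rose, 2 fell and 17 were not called (17 higher and 2 lower adjusted over the list alone), among them Aldh7a1 at 0.42 ± 0.09. The members that fell were Pcyt2, an enzyme of phosphatidylethanolamine synthesis, and the choline kinase gene Chkb, both at -0.37 ± 0.12, and 7 of the 11 fits without 1 library lost each call (largest adjusted p 0.0919 and 0.105). Both were named after their values were seen. Without MCD 2, genes called higher numbered 6 for fatty acid oxidation, 5 for bile acids, 6 for PXR and CAR targets and 4 for methionine. Bile acid genes called higher numbered 5 without MCD 5 or limonin 4, and methionine genes 5 without MCD 1. Those of the bile acid list called lower numbered 2 without limonin 3. PXR and CAR targets numbered 7 without MCD 1 and 6 without MCD 5, limonin 2, limonin 4 or limonin 6.

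Among 21 acute phase genes 5 rose, 1 fell and 15 were not called (5 higher and 1 lower adjusted over the list alone). Itih4, a protease inhibitor heavy chain, rose from 203 ± 35.1 to 599 ± 425 FPKM, and the lipopolysaccharide-binding protein gene Lbp rose by 1.04 ± 0.24. Hamp, the iron hormone hepcidin, was the member that fell, at -1.02 ± 0.33, and 7 of the 11 fits without 1 library lost that call (largest adjusted p 0.102), and those without MCD 5, limonin 3, limonin 5 or limonin 6 kept it. The call of Hamp was also lost with no filter, after each of the 3 scalings, after removal of length and GC trends and without both MCD 4 and 5. Smaller numbers rose in glucose metabolism (6 of 22, with 1 lower; 7 higher and 1 lower adjusted over the list alone) and cholesterol synthesis (3 of 24, with 1 lower; 0 higher and 1 lower adjusted over the list alone). The members that fell were Pkm, a pyruvate kinase of non-hepatocyte cells, at -1.13 ± 0.17 and Mvd, an enzyme of the mevalonate pathway, at -0.47 ± 0.11. The call of Mvd was lost after removal of length and GC trends, where its log2 fold change was -0.24 (adjusted p = 0.184). Acute phase genes called higher numbered 2 without MCD 1 or MCD 2 and 3 without MCD 5, limonin 2, limonin 4 or limonin 6, and glucose genes 2 without MCD 1 and 3 without MCD 2 or MCD 5. Cholesterol genes called higher numbered 0 without MCD 2, MCD 3, limonin 2 or limonin 4 and 1 without MCD 5, limonin 3 or limonin 6. With 1 library left out, genes called lower numbered up to 2 in each of the acute phase, glucose and cholesterol lists. The hepatocyte list had a median of 0.39. Medians were 0.21 for fatty acid oxidation, 0.34 for bile acids, 0.365 for methionine and 0.405 for PXR and CAR targets. They were 0.126 for glucose, 0.212 for cholesterol and 0.527 for acute phase genes. A larger share of hepatocyte RNA was not tested as a source of these rises.

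Camera called higher the hepatocyte list (adjusted p = 3.69e-06), the periportal list (2.29e-06), fatty acid oxidation (5.14e-07), bile acids (3.31e-05), PXR and CAR targets (5.14e-07), methionine (0.00014), acute phase (0.00383), glucose (0.0117) and cholesterol (0.0114). With an estimated correlation these adjusted p were 0.125, 0.145, 0.279, 0.125, 0.125, 0.263, 0.412, 0.279 and 0.561, and no call remained. Of all 35 lists tested, 20 were called at the preset correlation, 0 with the estimated correlation and 16 by fry, which asks only whether a list's genes move one way. Called by camera but not by fry were the cholesterol (fry adjusted p = 0.397), acute phase (0.219), glucose (0.0812) and female-biased (0.0855) lists. Of 100 drawn splits of the 11 libraries into 5 and 6, the real one included, 18 gave 20 or more called lists. The cholesterol call was lost without MCD 2 (adjusted p = 0.0712), without MCD 5 (0.0562) and without limonin 6 (0.0532). It was also lost with quantile normalization (0.0921), without both limonin 5 and 6 (0.0762) and without both MCD 4 and 5 (0.0861). With the replicate number as a block it was lost as well (0.0506). The glucose call was lost with a filter at 5 FPKM (0.131), with quantile normalization (0.0921) and without both limonin 5 and 6 (0.0762), and the acute phase call with quantile normalization (0.097).

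**Figure D3:**
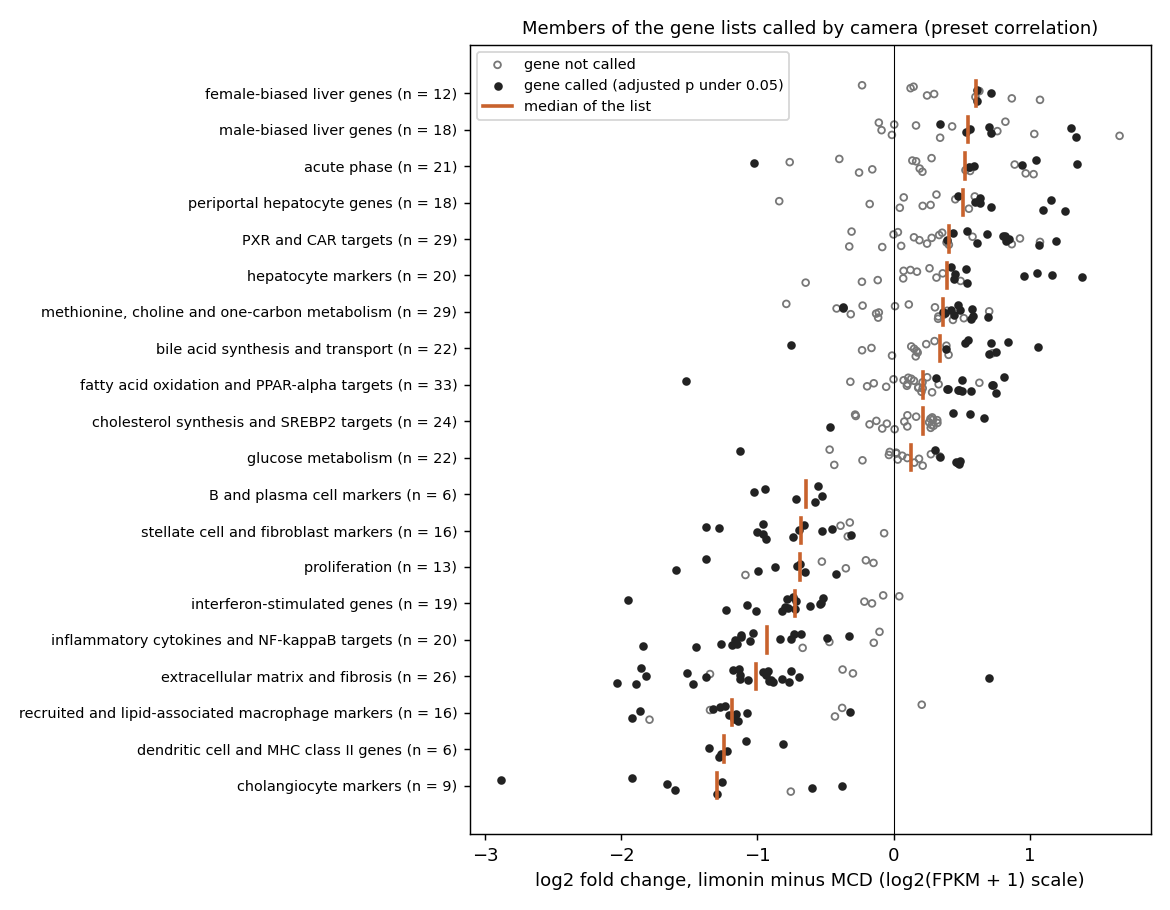
Log2 fold change of limonin against MCD (x axis) for each tested gene of the 20 lists called by camera at the preset correlation, with filled points for genes called by limma, open points for the others and an orange line at the list's median. The medians run from -1.29 for cholangiocyte markers to 0.61 for female-biased genes.

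Major urinary protein genes, which encode pheromone carriers made by male liver, included some of the largest increases. Mup11 (chromosome 4, 60658466 to 60662411, GRCm38) rose from 7.98 ± 2.61 FPKM (SD, n = 5) to 31.6 ± 18.2 (SD, n = 6), a log2 fold change of 1.77 ± 0.31. Mup18 rose by 2.19 ± 0.41 and Mup3 by 1.34 ± 0.23, each with 6 of 6 limonin libraries above every MCD library. Mup17 had the largest increase of all genes called higher, 3.78 ± 1.12 with an adjusted p of 0.0357; 8 of the 11 fits without 1 library lost this call, with adjusted p up to 0.0906, and those without MCD 4, limonin 3 or limonin 5 kept it. It was also lost without both limonin 5 and 6 and with the replicate number as a block. These genes are near-identical copies, so FPKM of single members are uncertain. Over the whole family 5 of 19 tested genes rose and 0 fell, and the summed FPKM was 1046 ± 373 in MCD and 1679 ± 618 with limonin (exact permutation p = 0.0541, two-sided, n = 5 and 6). The mean log2 level of the family was 1.08 higher with limonin (exact permutation p = 0.0281, two-sided). Of 18 genes known to be higher in male liver 7 rose and 11 were not called (11 higher adjusted over the list alone), and of 12 known to be higher in female liver 3 rose and 9 were not called (5 higher adjusted over the list alone). Male-biased genes called higher numbered 3 without MCD 2 and 4 without MCD 1, and female-biased genes 0 without MCD 1, MCD 2 or MCD 5, 1 without limonin 4, 5 or 6 and 5 without MCD 4. Camera called both lists higher, with adjusted p of 2.58e-06 and 0.00112, and with an estimated correlation both calls were lost (adjusted p = 0.125 and 0.302).

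The other lists were not called. Over all 10489 tested genes 759 rose and 1957 fell, so some calls in a list can occur without a shift of that list. Of 27 genes of endoplasmic reticulum stress and the integrated stress response 9 fell and 1 rose (12 lower and 1 higher adjusted over the list alone). Gdf15, a stress-induced cytokine, fell from 22.9 ± 8.66 FPKM (SD, n = 5) to 6.90 ± 3.26 (SD, n = 6). Atf3, which is also on the list of immediate early genes described below, fell by 1.58 ± 0.31. Ddit3, a transcription factor of prolonged stress, fell by 1.09 ± 0.22. Of 31 NRF2 and glutathione genes 4 rose and 3 fell (4 higher and 3 lower adjusted over the list alone), with the heme oxygenase gene Hmox1 at -1.13 ± 0.23 and catalase, Cat, at 0.56 ± 0.13. Of 23 lipogenesis genes 4 rose and 2 fell (4 higher and 2 lower adjusted over the list alone), with Me1, an NADPH-producing enzyme, at 0.59 ± 0.10 and the desaturase gene Scd2 at -0.93 ± 0.14. Of 26 genes of lipid uptake, droplets and lipoproteins 4 rose and 1 fell (2 higher and 1 lower adjusted over the list alone), with Mttp, which loads lipid onto lipoproteins, at 0.44 ± 0.09. Of 46 nuclear genes of oxidative phosphorylation 5 rose and 2 fell (5 and 2 adjusted over the list alone), and of 34 lysosome and autophagy genes 4 rose and 6 fell (4 and 6 adjusted over the list alone). Of 17 p53 and cell death genes 5 fell (5 adjusted over the list alone), of 14 ferroptosis and iron genes 1 rose and 3 fell (2 and 4 adjusted over the list alone), of 16 clock genes 2 rose (2 adjusted over the list alone) and of 8 targets of the aryl hydrocarbon receptor 1 rose (1 adjusted over the list alone). The last list was called higher without MCD 2 (adjusted p = 0.0359), limonin 2 (0.0311) or limonin 3 (0.0267) and with weights per library (0.0286). The p53 list was called lower with no filter (0.0109) and after removal of length and GC trends (0.0316). Of 6 blood genes 1 fell (1 adjusted over the list alone), and no gene was called among 5 adipose, 2 pancreatic and 2 sex-chromosome genes. Without MCD 2, lipogenesis genes called higher numbered 2, lipid uptake genes 1, oxidative phosphorylation genes 3 and lysosome genes 1, with 1 lysosome gene and 1 oxidative phosphorylation gene lower. Lysosome genes called higher numbered 1 also without MCD 1 or limonin 6, and 2 without MCD 3, MCD 5, limonin 2 or limonin 4. Oxidative phosphorylation genes called lower numbered 11 without limonin 5 and 5 without limonin 1, NRF2 genes 7 without limonin 3 and 6 without MCD 4, and p53 genes 8 without limonin 3. Lysosome genes called lower numbered 2 without MCD 5, limonin 2, limonin 4 or limonin 6 and 3 without MCD 1. Lipid uptake genes called higher numbered 1 without MCD 3 and 2 without MCD 1, MCD 4, limonin 2 or limonin 3. Lipid uptake genes called lower numbered 0 without MCD 1, MCD 2, MCD 5, limonin 2 or limonin 6, 2 without limonin 1 or limonin 5 and 4 without limonin 3. Lipogenesis genes called higher numbered 2 without MCD 3, MCD 5, limonin 2 or limonin 4, and those called lower 1 without MCD 1, MCD 2, limonin 2, limonin 5 or limonin 6. Stress response genes called higher numbered 2 without limonin 1, ferroptosis genes 2 without limonin 1, limonin 5 or limonin 6, and aryl hydrocarbon receptor targets 2 without MCD 2 or limonin 3. A clock gene was called lower without limonin 3, an adipose gene higher without MCD 4 and an adipose gene lower without limonin 1 or limonin 3. The medians of the lipid uptake, NRF2, oxidative phosphorylation, lysosome, pericentral, ferroptosis and adipose lists were below 0 while camera's direction was up, and so were their means except that of the pericentral list, 0.03. Camera compares a list with the other genes.

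Transcripts typical of other tissues were found in the libraries in unequal amounts. These values do not give their origin. Of the 12 largest increases, 8 were genes of sperm formation such as Prm1, Prm2 and Tnp2, which package sperm DNA. Prm1 rose from 2.34 ± 2.32 to 11.2 ± 7.63 FPKM with an adjusted p of 0.0499, and 8 of the 11 fits without 1 library lost this call (largest adjusted p 0.108), those without MCD 3, limonin 1 or limonin 2 keeping it. It was also lost with no filter, with the smaller pseudocounts, with the replicate number as a block, without both limonin 5 and 6 and without both MCD 4 and 5. The summed FPKM of 26 spermatid genes was 17.8 ± 16.4 in MCD (SD, n = 5) and 98.4 ± 62.8 with limonin (SD, n = 6), and was 0.68 in MCD 4 and 0.82 in MCD 5. These genes were picked because some were seen to rise, so the sum has no test. A further 30 spermatid genes summed to 11.6 ± 5.47 FPKM in MCD and 32.3 ± 18.7 with limonin (exact permutation p = 0.039 on the log2 sum, two-sided, n = 5 and 6). Of these, 2 were tested singly and 0 were called. The 30 genes are of the same tissue, in the same libraries, as the genes seen to rise. Their p therefore gives no separate support for a difference between the groups. Ropn1l alone held 4.34 to 8.36 FPKM per MCD library and 3.33 to 8.98 per limonin library. Of the 12 largest decreases, 4 were lacrimal or salivary gland genes, led by Mucl2 at -4.54 ± 1.43, whose call was lost in 9 of the 11 fits without 1 library (largest adjusted p 0.109) and kept without limonin 1 or limonin 3. It was also lost with no filter, with the smaller pseudocounts, with the replicate number as a block, at equal summed FPKM, without both limonin 5 and 6 and without both MCD 4 and 5. The summed FPKM of 14 such gland genes was 520 ± 105 in MCD and 263 ± 267 with limonin, where limonin 5 and 6 held 0 and 0.09 and limonin 1 held the most, 683. These lists, and those of heart and brain genes, were drawn up after the data had been seen.

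Beside the matrix, immune and hepatocyte groups, 11 of 15 immediate early and heat shock genes, which respond within minutes to tissue handling, fell and 4 were not called (12 lower adjusted over the list alone), among them Jun at -1.49 ± 0.22 and Fos at -0.96 ± 0.13. This list was not among the 35 lists adjusted together, so its p are unadjusted. Camera gave 3e-06 at the preset correlation and 0.0012 with an estimated correlation, and fry gave 2.83e-07. The p with an estimated correlation was the smallest of all lists. The mean log2 level was 3.85 ± 0.09 in MCD and 3.12 ± 0.12 with limonin (SD, exact permutation p = 0.00216, two-sided). An effect of tissue handling was not tested. Genes encoded by the mitochondrial genome took 18.4% to 22.8% of the summed FPKM in MCD and 13.1% to 16.4% with limonin, and 9 of 13 fell (12 adjusted over the list alone), among them mt-Nd3 at -1.08 ± 0.17. Without limonin 5 and 6, which differed from the rest in gland and heart genes, 2895 genes changed (1347 higher, 1548 lower), 2065 of them shared with the 2716. Without MCD 4 and 5, the libraries nearly free of spermatid genes, 1969 changed (486 higher, 1483 lower), 1870 of them shared.

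**Figure D4:**
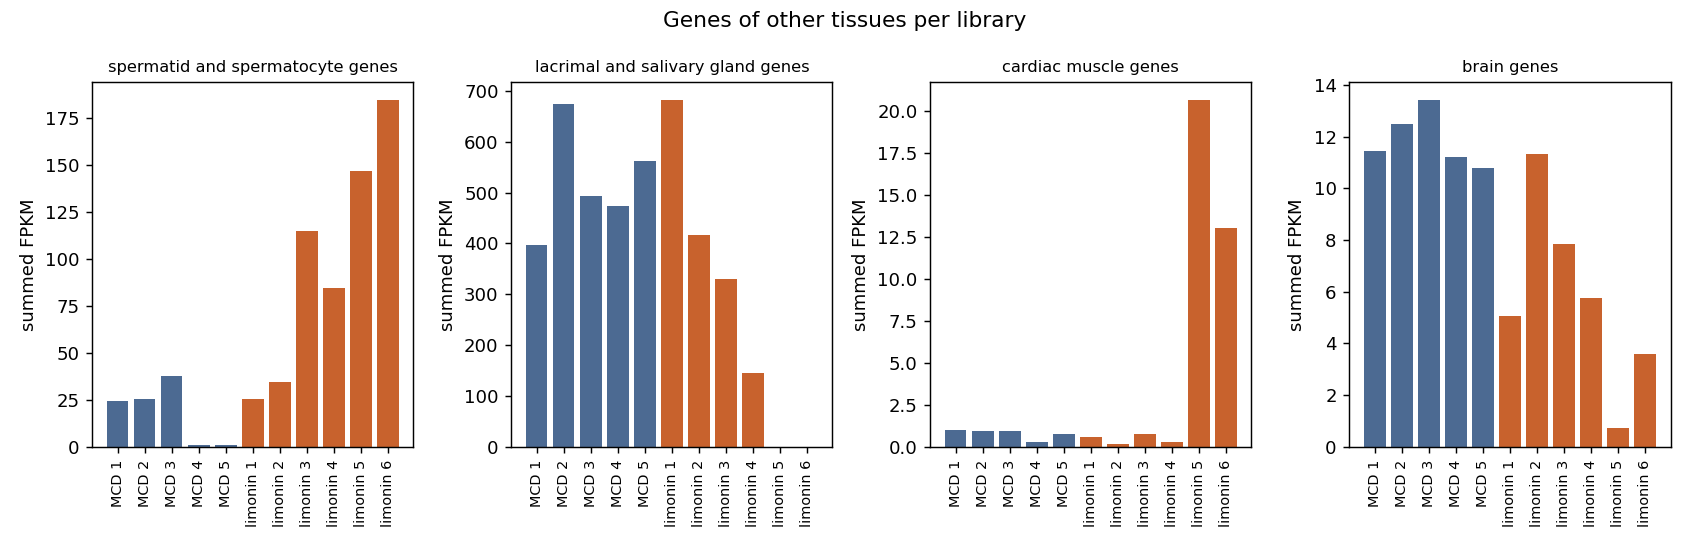
Summed FPKM per library (linear axes from 0) of genes typical of sperm formation, of lacrimal and salivary glands, of heart muscle and of brain, with MCD libraries in blue and limonin libraries in orange. Spermatid genes sum to 0.68 and 0.82 FPKM in MCD 4 and 5 and to 185 in limonin 6, and gland genes are at 0 and 0.09 in limonin 5 and 6.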

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

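The tests of a limonin response of spermatid genes, of a smaller share of all non-hepatocyte RNA, and of both explanations for the major urinary protein genes were chosen only after the results were seen.

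Spermatid genes picked because they were seen to rise with limonin were almost absent from MCD 4 and 5, and 7 of the 8 among the largest increases lost their calls in 3 to 9 of the 11 fits without 1 library. In 30 spermatid genes not looked at before, of which 2 were tested singly and 0 called, 29, or 96.7%, were higher both in MCD 1 to 3 than in MCD 4 and 5 and in limonin 3 to 6 than in limonin 1 and 2, where chance gives 25%; genes are not independent. This pattern within the groups is consistent with testis RNA or reads having entered libraries in different amounts, at dissection, at the bench or in a shared sequencing run. A response of the liver to limonin cannot be told apart for the difference between groups, since 1 limonin library lay within the range of the MCD libraries in mean log2 level, although by summed FPKM limonin 1 and 2 both did (25.5 and 34.2, MCD 0.68 to 37.7), as they did in the mean log2 level of the other 30 genes (0.41 in each, MCD 0.13 to 0.49). Overlap of some animals does not exclude a response in others, and no label names a sequencing batch, so the route was not tested.

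Of 26 tested matrix genes 22 fell with limonin, as did 11 of 16 macrophage and 8 of 9 bile duct markers (4 and 4 without MCD 2). A smaller share of all non-hepatocyte RNA would lower endothelial markers as well. The mean of stellate, macrophage and bile duct markers fell by 1.05 and that of endothelial markers by 0.12 on the log2 scale. The difference was -0.93 (exact permutation p = 0.00649, two-sided). The falling lists were pooled, and endothelial markers set against them, after their values were seen, so this p cannot exclude that explanation. Of 16 listed markers each, 9 were tested for bile ducts and 15 for endothelium. Kupffer cell markers, with a median of -0.44, were not in the comparison. A trend on transcript length and GC content was not the whole cause, since 21 of 22 matrix genes called lower, 95.5%, kept the call after these were removed. Limonin 5 and 6 alone were not the source, since the median of the matrix list was -0.949 without them and -1.01 with them. A response to limonin, and other differences between the animals such as food intake or the handling of tissue, stay open and were not tested.

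Of 19 tested major urinary protein genes 5 rose with limonin and 0 fell, and the rest were not called. Reads shared between near-identical copies cannot be told apart from a change of the family, since the summed FPKM differed with an exact permutation p of 0.0541. The mean log2 level of the members differed with an exact permutation p of 0.0281, but reads moved between copies can change that mean. A larger share of hepatocyte RNA cannot be told apart either, since the family rose more than hepatocyte markers with an exact permutation p of 0.126. Both tests were two-sided with 5 and 6 libraries.

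Of 100 drawn splits of the libraries, the real one included, 1 gave as many changed genes as the real split. The real split gave 2716 genes, and the others drawn gave at most 2. The other splits mix animals of both groups, which adds the group difference to the spread and lowers their counts. A difference in handling or batch that follows the groups would give the same result, so it is not excluded. For the lists chance cannot be excluded: 18 of the 100 splits gave 20 or more called lists, and the highest other split gave 26.

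Single libraries lay apart from the rest of their group in 23 of 440 groups of values tested, where chance gives about 1 in 20; the value given is the gap to the nearest library divided by the range of the group. In MCD 1 this was Cyp2c70 (0.831). In MCD 2 it was Fgg (0.726) and Trbc2 (0.805), in MCD 3 the implied depth (0.807), in MCD 4 Mup17 (0.896), and in MCD 5 Hlf (0.718) and the lipogenesis list (0.729). In limonin 1 it was Cyp2f2 (0.641) and Alas2 (0.656). In limonin 2 it was Cyp4a10 (0.806), Acsl1 (0.659), Fgg (0.632), Cps1 (0.647), Fga (0.652) and Eng (0.725). In limonin 3 it was Phlda3 (0.681), Ube2c (0.808), Gas6 (0.761), Retnlg (0.701), Cidec (0.672), the proliferation list (0.777) and the list of bile duct markers (0.643), and in limonin 5 Ugt2b35 (0.774). Heart muscle genes, too low to be tested, summed to 20.7 FPKM in limonin 5 and 13.02 in limonin 6 and to at most 1.01 in every other library.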

How the results depend on the processing

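The alternatives that left out limonin 5 and 6, MCD 4 and 5 or genes of other tissues, removed length and GC trends, or equalised summed FPKM were chosen only after results were seen. The 2716 changed genes became 1424 with a filter at 5 FPKM, where fewer genes were tested, and 5010 in the authors' deposited table, where all 31280 genes entered at a q under 0.05 with no limit on size; 3116 of these are among the 10489 tested here, and the authors marked 3333 with their added 1.5-fold limit (1168 higher, 2165 lower). Genes higher (759) became 412 with no filter, 1478 with median-ratio and 1813 with quantile scaling, 1347 without limonin 5 and 6, 486 without MCD 4 and 5, 1213 after removal of length and GC trends and 2682 in the authors' deposited table. Genes lower (1957) became 900 at 5 FPKM and 1117 at equal summed FPKM. Genes changed at least 2-fold (281) became 149 at 5 FPKM, 624 and 662 with pseudocounts of 0.1 and 0.01, which shrink low genes less, and 2203 in the authors' deposited table. The 20 lists became 0 with an estimated correlation. With each library left out, changed genes ran from 1408 to 3062, higher from 328 to 1097, lower from 1080 to 2134, those changed at least 2-fold from 171 to 379 and lists from 19 to 21. With the replicate number as a block there were 1257 changed genes, 362 higher, 895 lower and 178 changed at least 2-fold. That fit also leaves out limonin 6, and leaving out limonin 6 alone gave 2149, 699, 1450 and 240. Calls lost in the block fit included Col3a1 (adjusted p = 0.0553), Spp1 (0.0841), Ubd (0.133), Atf3 (0.0742), Gdf15 (0.0894) and Wfdc21 (0.0626). Correlations of same-numbered libraries ran from -0.235 to 0.204, which gives no clear sign that the numbers pair the animals. So few values cannot exclude a pairing, and the labels name none. Named genes that were not called turned direction in 3 cases, Cela1 at 0.031 after removal of length and GC trends and Ddx3y at 0.018 with quantile scaling and 0.016 without limonin 5 and 6. Of 156 named genes called, 79 kept the call in every alternative that tested them, at most 25, and 110 with each library left out. Of 20 lists called, 17 kept the call in every refit that tested them, at most 25, with the preset correlation. Except where stated, the cause was not tested. Count models, recovered reads and a second unit were not run, since the table used holds FPKM. Depth limits genes of low FPKM most.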

Other observations

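Pathway terms of the deposited table described further groups, and the terms and genes named here were chosen after their values were seen. Of 62 tested genes of complement and coagulation, proteins the liver secretes into blood, 23 rose and 8 fell (Fisher's exact test, one-sided, adjusted p = 4.04e-07 over 293 terms for the rise, against 9.7% of all genes with a term). Plg, the precursor of plasmin, rose from 163 ± 19.1 FPKM (SD, n = 5) to 287 ± 73.2 (SD, n = 6), a log2 fold change of 0.79 ± 0.15 with 6 of 6 limonin libraries above every MCD library, and F2, prothrombin, rose by 0.53 ± 0.11. Plau, which activates plasminogen, fell by 1.09 ± 0.22. Of 46 genes that degrade branched-chain amino acids 19 rose and 2 fell (adjusted p = 8.7e-07), among them Abat at 0.90 ± 0.17, and Oxct1, which uses ketone bodies, fell by 0.78 ± 0.12. Of 35 tryptophan genes 17 rose and 0 fell (adjusted p = 4.04e-07), with Kmo at 0.66 ± 0.13 and Tdo2 at 0.79 ± 0.18. Of 29 genes of the citrate cycle 12 rose and 1 fell (adjusted p = 0.000123), among them Sdha at 0.52 ± 0.10. These terms overlap with hepatocyte genes, and the test treats genes as independent.

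Among terms with lower genes, 42 of 89 genes of cytokines and their receptors fell and 5 rose (adjusted p = 4.12e-07), among them Ltb, a lymphotoxin chain, at -1.45 ± 0.20 and the chemokine gene Cx3cl1 at -0.98 ± 0.17. Of 129 genes of the actin cytoskeleton 49 fell and 5 rose (adjusted p = 3.61e-05). Actg1, a cytoplasmic actin, fell from 117 ± 23.4 to 57.3 ± 13.6 FPKM and the actin-binding gene Tmsb4x fell by 1.46 ± 0.23. In all, 40 terms were called for higher genes and 57 for lower genes.

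The median log2 fold change was -0.16 in the fifth of genes with the shortest transcripts and -0.01 in the fifth with the longest. Brain genes summed to 11.9 ± 1.08 FPKM in MCD and 5.71 ± 3.63 with limonin (SD, n = 5 and 6), and 3 of 3 tested fell; these genes were listed after the data had been seen.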
